A study of Mus musculus with 6 samples.

How the data were processed

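Single-cell RNA libraries were measured from crypt epithelial cells of the proximal small intestine of 6 male C57BL/6 mice that carry the Lgr5-eGFP-IRES-CreERT2 knock-in. Of these, 3 mice were young (3 months) and 3 were aged (22, 25 and 26 months for aged replicates 1, 2 and 3). Villi had been scraped off, crypts were released with EDTA and dissociated, and live cells that were EPCAM-high and negative for CD31, Ter119 and CD45 were sorted before capture with droplet 3' chemistry. Each mouse gave 1 library. The labels give no batch, date or litter, and the sorter used for each library was not given, so none of these could be tested or entered in a fit.

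The deposited matrices hold counts, that is unscaled UMI counts per gene and barcode, per the labels. Per the submitters' processing notes they were made with Cell Ranger 6.0.1 against mm10, while the annotation version, the intron setting and the cell-calling settings were not given in the sources used here. All values were whole numbers and the lowest barcode of a library held 500 to 662 UMIs, so barcodes had been selected before deposition. The files hold 38326 barcodes, 18703 young and 19623 aged. The series states 10844 cells, 5135 young and 5709 aged, without the filter that led to them, and the cells kept here are therefore not the same set. Genes were placed with GENCODE vM21 (mm10), in which 32235 of the 32285 gene identifiers were found (99.8%).

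Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs, which left 4122 young and 4581 aged. The median mitochondrial share over all barcodes was 43.1%, 40.6% and 42.5% in the young and 29.4%, 34.8% and 38.0% in the aged libraries, and this limit removed most of the barcodes left out. Doublets were scored with Scrublet in scanpy 1.11.5, and in each library the highest scores were removed at a rate of 0.8% per 1000 barcodes, which took out 94, 74 and 43 young and 139, 62 and 48 aged cells. Counts were scaled to 10000 per cell, and 2000 variable genes chosen per library, without mitochondrial, ribosomal or listed immune genes, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15).

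Clusters were named from 15 lists of cell type markers, of which 7 intestinal epithelial classes were given names in these data. A cluster took the class with the highest mean standardised marker level. It stayed unnamed where fewer than 3 markers of that class were detected (25% of cells, 1.5-fold above the other cells), where another class had more markers among its top 10 genes, where 5 of these 10 were DNA replication genes, or where the score was under 0.4 or led the next by under 0.1. A shallow cluster needed 4 markers among its top 10. The conditions on replication genes, the lead and shallow clusters were added after first clusterings had been seen, as was a fixed numerical environment, since another environment had given another partition. Names end in "-like" because they rest on marker levels alone. Clusters that no class claimed held 39.1% ± 3.82 of the young and 40.6% ± 5.87 of the aged epithelial cells (SD, n = 3 mice each; exact permutation p = 0.6), and they were used in the sums over all cells only.

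UMIs were summed per mouse, over all kept epithelial cells and over each class with at least 20 cells in every library. Sums were compared with the edgeR 4.0.16 quasi-likelihood test (filterByExpr, TMM, R 4.3.3), with the mouse as replicate and p-values adjusted after Benjamini and Hochberg over the genes of a class. A gene was called at an adjusted p under 0.05. Fold changes are log2, aged over young, with a standard error from the fold change and its F statistic, and levels are in CPM, the UMIs of a gene relative to all UMIs of the sum, as mean ± SD over 3 mice per group. Whether an age effect differed between classes was tested as the class by age term with the mouse as a block. Cell shares were compared by a two-sided exact permutation test, which with 3 against 3 mice cannot go below 0.1. A gene whose 3 young and 3 aged values do not overlap is expected for 10% of genes by chance.

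In all, 31 pathway lists and 15 marker lists were written before the data were examined, as were the filters, tests, thresholds and the rule for named genes. Each pathway list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, which asks whether its genes stand higher or lower than the other genes. The same test with a correlation estimated per list, and fry, which asks whether a list's genes move one way on balance, stand beside it. List tests in the goblet-like and tuft-like classes were added after the data had been seen. The counts of members "adjusted over the list alone" come from adjusting the gene test over that list's members.

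Genes named in the text are those with an adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between the groups. Of these the 10 largest rises and the 10 largest falls were taken (5 and 5 in the goblet-like and tuft-like classes). Named too were, for each list described, up to 4 called members with the smallest adjusted p or else the 2 with the highest mean CPM, and a fixed set of 18 genes, among them Lgr5, Olfm4, Ascl2, Mki67, Lyz1, Muc2, Chga, Dclk1, Cd74, H2-Ab1, Reg3b, Reg3g, Cdkn1a, Cdkn2a, Fabp1 and Apoa4. Predicted genes known only by a clone or model number were counted but not named. Members of lists that were named for their call after adjustment over the list alone, or for cell composition, were chosen after their values had been seen.

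Depth per library ran from 51631611 to 78500525 UMIs, and kept cells held a median of 17587 to 21126 UMIs. Within a group, total counts per gene differed between mice 21.8 to 44.8 times more than counting error alone would give (chi-square per degree of freedom). Intervals (95%, exact Clopper-Pearson) and floors (3 counts of the total) cover counting error only. The edgeR test was checked on simulated data made from these sums with 200 changed genes. Of the 2-fold changes it recovered 76.1% in all cells, 74.6% in stem-like, 79.1% in cycling-like and 85.1% in absorptive-like sums. In goblet-like and tuft-like sums it recovered 61.2% and 50.7%, and false calls made up 2.50% to 7.69% of the calls. Simulated genes were drawn independently at the trended dispersion. These rates therefore leave out correlation between genes and structure among the mice, and real false calls may be more frequent.

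The replicate numbers of the titles were checked for pairs, by correlating the deviations of each young and each aged library from their group. Only in the goblet-like class did every pair of equal numbers correlate above 0.1 (0.124, 0.104 and 0.238), so the fit with the number as a block is given beside that class's count and elsewhere with the alternatives.

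The alternatives were the DESeq2 1.42.0 Wald test, its size factors in the edgeR test, no filter on low counts, the replicate number as a block, a stricter filter (2000 UMIs, 1000 genes, 10% mitochondrial) and a looser one (500, 250 and 30%), no doublet removal, Leiden resolution 2, values centred by library before clustering, clustering without the called genes, other denominators for shares, and each library left out in turn. After the data had been seen, a limit of 25% mitochondrial UMIs, 5 further clustering seeds, the largest and the highest-scoring cluster of a class alone, and the named classes as denominator were added.

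Barcodes above the mitochondrial limit were left out because cells that are dying hold such shares, and they were used only to check genes found in the kept cells. A cluster of 392 shallow cells led by Lars2 (median 1315 UMIs) had no epithelial markers in place and was left out of the epithelial sums. Paneth-like and enteroendocrine-like cells were too few for a gene test, and only their values are given.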

Results

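Crypt epithelial cells of the proximal small intestine were compared between 3 young and 3 aged male mice, with 1 droplet library per mouse. The question was which transcripts and which cell types differ with age. The young libraries held 65644208, 62218819 and 51631611 UMIs over 7170, 6523 and 5010 barcodes. The aged libraries held 78500525, 53874869 and 58949052 UMIs over 8173, 5175 and 6275 barcodes. After the cell filters and doublet removal, 1468, 1313 and 1012 epithelial cells stayed in the young and 1791, 1403 and 864 in the aged libraries. Levels are in CPM, as mean ± SD over the 3 mice of a group. Fold changes are log2 of aged over young ± SE, and n = 3 mice per group throughout.

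Cells fell into stem-like, cycling-like, absorptive-like, goblet-like, Paneth-like, tuft-like and enteroendocrine-like classes, and 5 of these had enough cells for a gene test. Paneth-like cells, which carried the lysozyme gene Lyz1 and defensins, made up 0.114% ± 0.197 of young and 1.29% ± 0.472 of aged epithelial cells. The aged values (0.782%, 1.71% and 1.39%) lay above the young ones (0.341%, 0 and 0). Young replicate 1 held 5 such cells of 1468, with a 95% exact interval of 0.111% to 0.793%. In the other young libraries 0 of 1313 and 0 of 1012 cells were Paneth-like. Their floors were 0.228% and 0.296%, taken as 3 counts of the total and not as exact intervals. Stem-like cells made up 19.3% ± 4.93 of young and 20.4% ± 3.56 of aged cells, and cycling-like cells 12.9% ± 3.26 and 12.4% ± 2.73. Absorptive-like cells made up 13.7% ± 6.75 and 9.84% ± 3.12, and goblet-like cells 9.33% ± 1.79 and 8.10% ± 3.55. Tuft-like cells made up 4.82% ± 0.684 and 6.84% ± 3.12. Enteroendocrine-like cells, the hormone producers, made up 0.818% ± 0.296 and 0.424% ± 0.239, and cells without a class name 39.1% ± 3.82 and 40.6% ± 5.87. The two-sided exact permutation test, which cannot go below 0.1 here, gave 0.1 for Paneth-like, 0.2 for enteroendocrine-like and 0.4 for tuft-like cells. It gave 0.6 for absorptive-like, 0.7 for goblet-like, 0.8 for stem-like and 1 for cycling-like cells, and no share passed after adjustment over the 7 classes and the unnamed cells together (lowest adjusted p 0.8). The stem-like class joins a cluster led by Olfm4, Gkn3 and Lgr5 (787 cells) and another led by Atad2, Clspn and Lig1 (799 cells), whose DNA replication genes stayed just under the limit at which a cluster was left unnamed. The latter gave 51.7% ± 5.60 of the class in young and 50.1% ± 4.13 in aged mice, so stem-like results rest in good part on cells with replication genes.

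**Figure D1:**
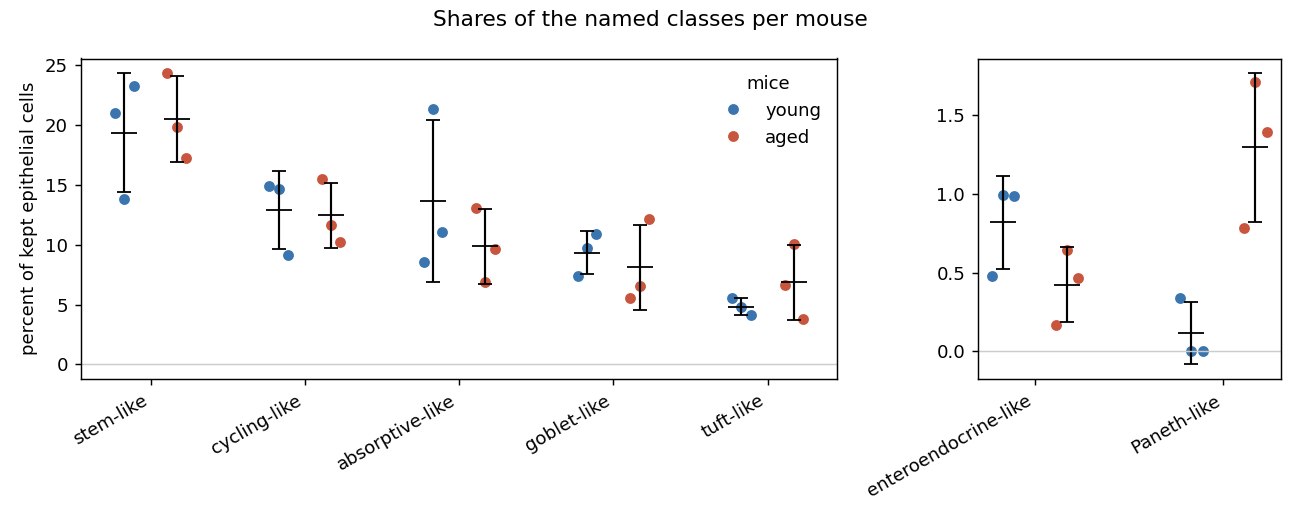
Share of each class among the kept epithelial cells of a mouse, in percent, with dots for the 3 young and 3 aged mice and bars for mean ± SD. The aged mice lie above the young mice for Paneth-like cells (1.29% against 0.114% on average), where the lower end of the young SD reaches below 0.

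Over all kept epithelial cells, genes that present antigen on MHC class II stood higher in aged mice. H2-Aa, the class II alpha chain, rose from 45 ± 4.25 to 209 ± 79.6 CPM (2.24 ± 0.24, adjusted p = 0.0149). The beta chain gene H2-Eb1 rose from 76.6 ± 1.47 to 222 ± 77.2 (1.57 ± 0.21, adjusted p = 0.0247). H2-DMb1, which helps to load peptides, rose from 17.2 ± 0.834 to 53.2 ± 21.1 (1.65 ± 0.24, adjusted p = 0.0351). The invariant chain gene Cd74 stood at 452 ± 13.4 in young and 1037 ± 338 in aged mice and did not pass (1.23 ± 0.20, adjusted p = 0.0521). The class II gene H2-Ab1 stood at 111 ± 2.61 and 298 ± 119 and did not pass either (1.46 ± 0.24, adjusted p = 0.0501). Without young replicate 3 these calls ended (adjusted p = 0.133 for H2-Aa, 0.200 for H2-Eb1 and 0.249 for H2-DMb1). H2-Eb1 was also lost without young replicate 2 (0.0876), and H2-DMb1 without young replicates 1 (0.0577) and 2 (0.108).

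Outside the MHC, Ceacam10, of the carcinoembryonic antigen family, rose from 40.7 ± 11.7 to 139.6 ± 18.8 CPM over all cells (1.80 ± 0.20, adjusted p = 0.0149). Ly6e, which codes for an interferon-inducible membrane-anchored protein, rose from 105 ± 15.4 to 233 ± 16.8 (1.18 ± 0.13, adjusted p = 0.0149). Nrn1, which codes for neuritin, fell from 7.67 ± 0.506 to 1.35 ± 0.532 (-2.42 ± 0.25, adjusted p = 0.0149). The iron exporter gene Slc40a1 fell from 10.7 ± 2.72 to 3.85 ± 0.726 (-1.46 ± 0.22, adjusted p = 0.0380). Also higher were the tyrosine phosphatase gene Ptpn6 (1.06 ± 0.11, adjusted p = 0.0149) and the kinase gene Matk (0.72 ± 0.11, 0.0380). Inside the MHC, Ly6g6f rose (1.06 ± 0.17, 0.0493). Matk was among the leading genes of the tuft-like cluster. The summed tuft markers stood at 170 ± 22.3 CPM in young and 291 ± 92.1 in aged mice. Under the stricter cell filter 25 genes were called, of which 6 were among the 34 called here, and the sign of Matk turned (-0.23). H2-Aa, H2-Eb1, H2-DMb1, Ceacam10 and Nrn1 passed there, while Ly6e, Ptpn6, Slc40a1 and Ly6g6f did not. In all, edgeR called 34 of 12843 genes, 20 higher and 14 lower. Of all genes 902 had an unadjusted p under 0.05, and 12.6% showed no overlap between the groups, against 10% by chance. The count was 19 without young replicate 2, 13 without aged replicate 2 and 77 without aged replicate 3. Without young replicate 3 edgeR called 0 genes (875 at an unadjusted p under 0.05). Ceacam10, Ly6e, Ptpn6 and Nrn1 were then at 0.133, Slc40a1 at 0.200, and Ly6g6f and Matk at 0.257. Slc40a1 was also lost without young replicate 2 and aged replicates 1 and 2 (0.0772 to 0.155). Ly6g6f was also lost without young replicates 1 and 2 and aged replicate 2 (0.0574 to 0.149), and Matk without any library but aged replicate 3 (0.0611 to 0.257). DESeq2 called 147 genes and the edgeR test without a low-count filter 296. With the replicate number as a block edgeR called 0 (893 at an unadjusted p under 0.05).

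Other genes of interest did not pass over all cells. Lyz1 stood at 97.3 ± 67.2 in young and 933 ± 589 CPM in aged mice (3.27 ± 0.57, adjusted p = 0.0618). Chga, of the granules of hormone-producing cells, stood at 29.5 ± 16.9 and 7.18 ± 5.10 (-2.05 ± 0.56, adjusted p = 0.269). The stem cell genes Lgr5 and Ascl2 were at -0.14 ± 0.29 and 0.28 ± 0.31. The cell cycle inhibitor gene Cdkn1a was at -0.33 ± 0.24. Cdkn2a, a marker used for senescence, had 1, 2 and 1 UMIs in the young and 1, 1 and 3 in the aged libraries and was not tested.

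Of the 31 pathway lists, camera called 11 over all cells. The MHC class II list rose (8 of 9 tested genes higher, median 1.23, adjusted p = 3.28e-12, and adjusted p = 0.842 with an estimated correlation). Of its members 3 were called over all genes and 7 when adjusted over the list alone, the latter with Cd74, H2-Ab1, H2-DMa and the class II regulator gene Ciita. MHC class I rose (22 of 26 higher, 0 called, 6 adjusted over the list alone, adjusted p = 2.33e-06, and adjusted p = 0.842 with an estimated correlation). Its most abundant members B2m and Calr were at 0.23 ± 0.18 and -0.35 ± 0.16. The interferon-gamma (17 of 25 higher), type I interferon (23 of 31), antimicrobial (19 of 30), mitochondrially encoded (11 of 13) and ribosomal protein (53 of 77) lists rose. Each of these was at an adjusted p of 0.0101 with 0 members called, and at adjusted p = 0.842 with an estimated correlation. In the antimicrobial list 10 members were higher and 4 lower when adjusted over the list alone. The higher ones were Lyz1, Itln1 and 8 defensin genes such as Defa24 (470.1 ± 382 CPM in young and 4194 ± 2826 in aged mice). These defensin genes of Paneth cells are near-identical, so their reads are hard to assign singly. The lower ones were Reg4 and the gasdermin genes Gsdmc2, Gsdmc3 and Gsdmc4. The summed Paneth markers stood at 1016 ± 911 CPM in young and 8105 ± 5658 in aged mice. Fatty acid oxidation (33 of 44 lower, adjusted p = 0.00625) and the unfolded protein response (20 of 27 lower, adjusted p = 0.0101) fell with 0 members called, both at adjusted p = 0.842 with an estimated correlation. Dissociation and immediate early genes (29 of 31 lower, adjusted p = 0.00153) and epithelial junctions (19 of 28 lower, adjusted p = 0.0173) fell too, with Muc3 and Cldn4 lower when adjusted over the junction list alone. Hspa8, the most abundant dissociation gene, stood at 2899, 1241 and 2819 CPM in young and 2119.9, 1626 and 1351 CPM in aged mice, so young replicate 2 lay below the aged mice and the other young mice above them. All 11 lists were at adjusted p = 0.842 with an estimated correlation. Neither that test nor fry called any list (0 of 31, with 1 and 2 lists at an unadjusted p under 0.05). With each library left out in turn, MHC class II (highest adjusted p 7.24e-08), MHC class I (0.00417) and dissociation genes (0.0240) passed in 6 of 6 fits. Without young replicate 3 the interferon-gamma (0.0509), type I interferon (0.111), antimicrobial (0.172), unfolded protein (0.111), ribosomal (0.517) and junction lists (0.111) were lost. Without aged replicate 2 the type I interferon (0.107), fatty acid (0.0954), unfolded protein (0.161), ribosomal (0.121) and junction lists (0.330) were lost, and the count of lists was 7. Without aged replicate 3 the interferon-gamma (0.443), antimicrobial (0.231) and mitochondrial lists (0.0545) were lost. Without young replicate 2 fatty acid oxidation (0.516), mitochondrial (0.0837) and junction lists (0.0883) were lost. Without young replicate 1 both interferon lists (0.0694 and 0.218) and the unfolded protein list (0.0540) were lost, the last also without aged replicate 1 (0.126).

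In stem-like cells, antigen presentation genes were among those that rose. H2-Aa rose from 61.2 ± 12.8 to 232 ± 89.1 CPM (1.95 ± 0.21, adjusted p = 1.44e-04). H2-Ab1 rose from 134 ± 16.4 to 350.4 ± 143 (1.40 ± 0.20, adjusted p = 0.00241). H2-Eb1 rose from 112 ± 21.4 to 284 ± 107 (1.36 ± 0.20, adjusted p = 0.00332). Cd74 rose from 564 ± 76.2 to 1128 ± 390 (1.02 ± 0.18, adjusted p = 0.0117). Psmb8, a subunit gene of the immunoproteasome, rose from 163 ± 5.18 to 469.7 ± 192 (1.55 ± 0.19, adjusted p = 9.47e-04). Also higher were H2-DMb1 (1.31 ± 0.20, adjusted p = 0.00497) and the immunoproteasome subunit gene Psmb9 (1.18 ± 0.19, adjusted p = 0.00542). The peptide transporter gene Tap1 (1.28 ± 0.25, adjusted p = 0.0322) and the class I gene H2-Q7 (1.89 ± 0.29, adjusted p = 0.00475) were higher too. Reads of H2-Q7 are uncertain because H2-Q6 is near-identical. The annotated spans of Psmb9 and Tap1 overlap slightly, and whether this affects their reads was not tested. Without young replicate 3 Cd74 (adjusted p = 0.114), H2-Eb1 (0.0564), H2-DMb1 (0.0691), Psmb9 (0.0859) and Tap1 (0.245) no longer passed. Tap1 was also lost without young replicates 1 (0.131) and 2 (0.0592) and in the Lgr5-led cluster alone (0.228, with 1.85e-14 to 0.883 over all alternatives).

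Outside the MHC, the interferon-inducible GTPase gene Igtp rose from 3.32 ± 0.988 to 11.6 ± 4.24 CPM in stem-like cells (1.83 ± 0.31, adjusted p = 0.0102). Ceacam10 rose from 67.1 ± 15.3 to 203 ± 20.3 (1.61 ± 0.15, adjusted p = 5.46e-05). Ly6e rose from 90.9 ± 19.3 to 241 ± 12.5 (1.42 ± 0.14, adjusted p = 6.55e-05). Ptpn6 rose from 11.3 ± 0.449 to 32 ± 3.64 (1.51 ± 0.15, adjusted p = 7.47e-05), and Cyyr1 from 4.76 ± 1.19 to 12.2 ± 2.12 (1.44 ± 0.24, adjusted p = 0.0101). Nrn1 fell from 13.7 ± 2.35 to 3.51 ± 1.45 (-1.88 ± 0.25, adjusted p = 0.00173). Cox6b2, a cytochrome c oxidase subunit gene, fell from 10.03 ± 0.672 to 2.75 ± 0.195 (-1.81 ± 0.25, adjusted p = 0.00173). Maged1, of the MAGE family, fell from 17.8 ± 3.68 to 7.52 ± 1.01 (-1.24 ± 0.19, adjusted p = 0.00497). In all, edgeR called 34 of 10549 genes, 24 higher and 10 lower. Of all genes 684 had an unadjusted p under 0.05, and 11.9% showed no overlap (10% by chance). The count was 15 without young replicate 3, where Maged1 (adjusted p = 0.0691), Igtp (0.102) and Cyyr1 (0.0989) were lost. Igtp (0.0641) and Cyyr1 (0.0501) were also lost without young replicate 1, and Cyyr1 without aged replicate 1 (0.0674). In the Lgr5-led cluster alone, taken after the data had been seen, 24 genes were called, 22 of them shared, and Igtp was not (0.663, with 8.81e-09 to 0.689 over all alternatives). The count was 157 without a low-count filter, 81 with the replicate number as a block, 10 under the stricter cell filter and 19 after centring by library. It was 20 at the limit of 25% mitochondrial UMIs, and 18, 14, 21 and 20 under 4 of the 5 further clustering seeds.

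The stem cell genes themselves did not pass in this class. Lgr5, the receptor gene that marks crypt stem cells, stood at 24.6 ± 3.15 in young and 17.8 ± 5.35 CPM in aged mice (-0.38 ± 0.18, adjusted p = 0.764). Olfm4 stood at 3550.1 ± 428 and 3184 ± 657 (-0.14 ± 0.12, adjusted p = 0.908), and Ascl2 at 50.6 ± 3.19 and 52.4 ± 15.9 (0.11 ± 0.16, adjusted p = 0.951).

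Camera called 7 lists in stem-like cells. MHC class II rose (8 of 9 higher, median 1.02, 6 called, 7 adjusted over the list alone, adjusted p = 1.28e-17), with adjusted p = 0.447 with an estimated correlation. MHC class I rose (21 of 24 higher, 4 called, 10 adjusted over the list alone, adjusted p = 7.38e-12, and adjusted p = 0.781 with an estimated correlation). The interferon-gamma list rose (15 of 18 higher, 1 called, adjusted p = 4.51e-05), with 4 members, among them Igtp, Irgm1 and Parp14, higher when adjusted over the list alone. It was at adjusted p = 0.781 with an estimated correlation. The mitochondrially encoded list rose (11 of 13 higher, adjusted p = 0.00997, and adjusted p = 0.447 with an estimated correlation), with mt-Nd6 and mt-Atp8 higher when adjusted over the list alone. As over all cells, the level of this list depends on the mitochondrial filter. Genes of mitosis (33 of 44 higher) and ribosomal proteins (46 of 77 higher) rose, both at an adjusted p of 0.0408 and at adjusted p = 0.880 with an estimated correlation, with Top2a at 0.22 ± 0.10. Genes of DNA replication fell (37 of 48 lower, adjusted p = 0.00227), with Pcna at -0.01 ± 0.12. None of these last lists had a called member, over all genes or adjusted over the list alone, and adjusted p was 0.843 to 0.880 with an estimated correlation. The lists of stem cell genes (median 0.01, adjusted p = 0.449), Wnt targets (0.02, 0.744), Notch (0.03, 0.432), p53 targets (0.01, 0.766) and senescence (-0.04, 0.841) did not pass. No list passed with an estimated correlation or by fry (0 of 31, each with 2 lists at an unadjusted p under 0.05). Both MHC lists, interferon-gamma and the mitochondrial list passed with each library left out (highest adjusted p 0.0486). DNA replication was lost without young replicate 3 (0.506) and aged replicates 1 (0.136) and 2 (0.0755). Mitosis was lost without young replicate 2 (0.681) and aged replicate 2 (0.792), and ribosomal proteins without young replicate 3 (0.565) and aged replicate 2 (0.542). The count of lists was 12 without aged replicate 1 and 4 without aged replicate 2.

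**Figure D2:**
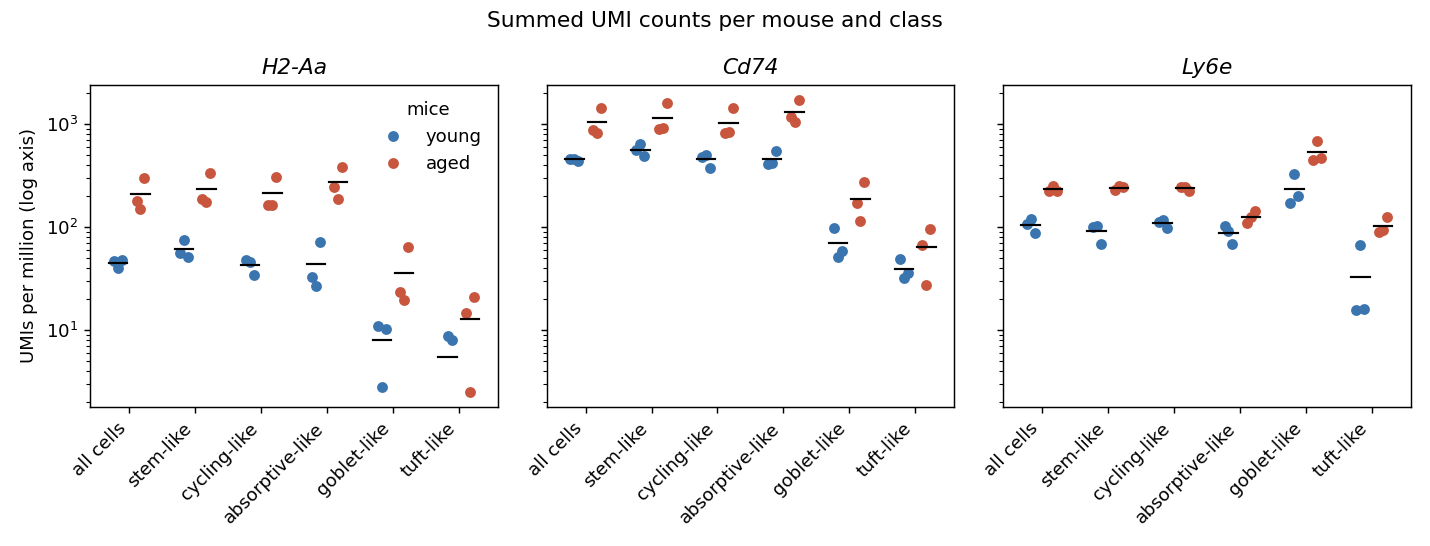
Levels of H2-Aa, Cd74 and Ly6e in CPM on a log axis, by class, with a dot per mouse (young blue, aged red) and bars for the mean. In stem-like cells the aged mean of H2-Aa was 232 CPM against 61.2 in young mice, and a young tuft-like H2-Aa value of 0 lies off the axis.

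In cycling-like cells presentation genes rose as well. H2-Aa rose from 42.7 ± 7.32 to 212 ± 83.4 CPM (2.31 ± 0.22, adjusted p = 3.58e-04). H2-Eb1 rose from 69.4 ± 9.07 to 199 ± 69.99 (1.53 ± 0.19, adjusted p = 0.00314). Cd74 rose from 452 ± 71.5 to 1025 ± 338 (1.22 ± 0.18, adjusted p = 0.0138). Also higher were H2-DMb1 (1.77 ± 0.26, adjusted p = 0.0128), H2-Ab1 (1.46 ± 0.23, adjusted p = 0.0165), Psmb8 (1.41 ± 0.19, adjusted p = 0.00501) and Psmb9 (1.14 ± 0.19, adjusted p = 0.0224). Without young replicate 3 the calls of Cd74 (adjusted p = 0.112), H2-Ab1 (0.156), H2-DMb1 (0.0661), Psmb8 (0.0609) and Psmb9 (0.188) ended. Psmb9 was also lost without young replicate 1 (0.0820) and aged replicate 2 (0.114).

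Among the other genes of cycling-like cells, Ly6e rose from 109 ± 10.7 to 238 ± 11.1 CPM (1.17 ± 0.10, adjusted p = 1.78e-04). Ceacam10 rose from 33.8 ± 14 to 126 ± 18.4 (1.87 ± 0.21, adjusted p = 0.00145), and Ptpn6 from 7.69 ± 1.82 to 20.7 ± 0.85 (1.41 ± 0.19, adjusted p = 0.00501). Adh6a, an alcohol dehydrogenase gene, fell from 115.5 ± 19.8 to 39.6 ± 12.6 (-1.51 ± 0.18, adjusted p = 0.00314). Reg1, which codes for a secreted lectin, fell from 181 ± 67 to 84.5 ± 3.13 (-1.07 ± 0.19, adjusted p = 0.0377). The gasdermin genes Gsdmc4 (-2.21 ± 0.36, adjusted p = 0.0204) and Gsdmc2 (-2.30 ± 0.43, adjusted p = 0.0474) fell, with reads that near-identical copies share. The proliferation marker Mki67 stood at 218 ± 2.82 in young and 209.6 ± 10.6 in aged mice (adjusted p = 0.987). In all, edgeR called 24 of 9884 genes, 19 higher and 5 lower. Of all genes 825 had an unadjusted p under 0.05, and 14.8% showed no overlap (10% by chance). The count was 8 without young replicate 3, 14 without aged replicate 2 and 50 without aged replicate 3. Gsdmc2 was lost without young replicates 2 (0.135) and 3 (0.188) and aged replicates 1 (0.147) and 2 (0.213). Gsdmc4 was lost without young replicate 3 (0.0609) and aged replicates 1 (0.0806) and 2 (0.156), and Reg1 without aged replicates 1 (0.0960) and 2 (0.205). DESeq2 called 38 genes, the test without a low-count filter 196, the fit with the replicate number as a block 39, and the first further clustering seed 37.

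Camera called 17 lists in cycling-like cells, of which 6 rose. MHC class II rose (8 of 9 higher, median 1.35, 6 called, 7 adjusted over the list alone, adjusted p = 1.32e-15, and adjusted p = 0.355 with an estimated correlation). MHC class I rose (20 of 23 higher, 2 called, adjusted p = 6.07e-06), with 8 members higher and Calr lower when adjusted over the list alone, and adjusted p = 0.371 with an estimated correlation. Ribosomal protein genes rose together (73 of 77 higher, median 0.14, 12 adjusted over the list alone, adjusted p = 7.34e-18, and adjusted p = 0.355 with an estimated correlation). The stem cell signature rose (22 of 27 higher, median 0.25, adjusted p = 6.37e-05, and adjusted p = 0.369 with an estimated correlation), with Olfm4 at 557 ± 16.1 in young and 659.7 ± 300.5 CPM in aged mice. Nuclear genes of oxidative phosphorylation (47 of 75 higher, adjusted p = 0.00507) and the mitochondrially encoded list (11 of 13 higher, adjusted p = 0.0234) rose too. These were at adjusted p = 0.441 and 0.355 with an estimated correlation. The unfolded protein response list fell (21 of 25 lower, adjusted p = 1.71e-05, and adjusted p = 0.369 with an estimated correlation), with the chaperone genes Hspa5 at -0.36 ± 0.15 and Hsp90b1 at -0.29 ± 0.11. Hspa5 stood at 504, 310.2 and 534 CPM in young and 348, 331 and 336 CPM in aged mice, so young replicate 2 lay below the aged mice here too. Fatty acid oxidation (31 of 39 lower, adjusted p = 0.00108), brush border (16 of 22, 0.00276), glycolysis (17 of 23, 0.00507) and oxidative stress genes (30 of 41, 0.0169) fell, at adjusted p = 0.355 to 0.371 with an estimated correlation. Iron handling (11 of 16 lower, adjusted p = 0.0145), dissociation genes (20 of 24, 0.00628), junctions (21 of 26, 0.00507) and the circadian clock (6 of 8, 0.0169) fell as well, also at adjusted p = 0.355 to 0.371 with an estimated correlation. So did the lists of duodenal (11 of 12 lower, adjusted p = 3.80e-04) and ileal position (7 of 10, 0.0234), both at adjusted p = 0.355 with an estimated correlation. When adjusted over the list alone, Alpi of the brush border and Pkm and Ldha of glycolysis were lower. So were Slc40a1 and the ferritin gene Fth1 of iron handling and Cry1 of the clock, as well as Rbp2 and Onecut2 of the duodenal and Muc3 and Lypd8 of the ileal list. Neither the test with an estimated correlation nor fry called a list (0 of 31, with 3 and 6 lists at an unadjusted p under 0.05). Both MHC lists, ribosomal proteins, unfolded protein response, brush border, glycolysis, junctions and the duodenal list passed with each library left out. The stem cell signature was lost without aged replicate 2 (0.0685), oxidative phosphorylation without young replicate 3 (0.130), and dissociation genes without young replicate 1 (0.511). Fatty acid oxidation (0.156) and oxidative stress (0.461) were lost without young replicate 2 and the clock without aged replicate 3 (0.0624). The mitochondrial list was lost without young replicates 1 (0.0524) and 2 (0.0827) and aged replicate 1 (0.114). Iron handling was lost without young replicate 3 (0.0525) and aged replicate 1 (0.0635), and the ileal list without young replicates 2 (0.0754) and 3 (0.0536).

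In absorptive-like cells MHC class II genes rose. H2-Aa rose from 43.7 ± 24.1 to 272 ± 103 CPM (2.69 ± 0.30, adjusted p = 3.61e-04). H2-Eb1 rose from 61.9 ± 17.4 to 247 ± 86 (2.01 ± 0.21, adjusted p = 3.12e-04). H2-DMb1 rose from 22.5 ± 5.73 to 79.4 ± 17 (1.86 ± 0.17, adjusted p = 2.77e-04). Cd74 rose from 455 ± 77.2 to 1308 ± 361 (1.53 ± 0.16, adjusted p = 3.12e-04), and H2-Ab1 from 103 ± 28.3 to 332 ± 101 (1.70 ± 0.19, adjusted p = 4.02e-04). Psmb8 (1.21 ± 0.16, adjusted p = 0.00282) and Psmb9 (0.90 ± 0.17, adjusted p = 0.0411) rose too. Outside the MHC, Ceacam10 rose from 11.9 ± 4.29 to 57.3 ± 26.5 (2.37 ± 0.31, adjusted p = 0.00198). The class II genes and Ceacam10 passed with each library left out. Psmb8 was lost without young replicate 3 (adjusted p = 0.0588), and Psmb9 without any young replicate and without aged replicate 2 (0.0672 to 0.253).

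Among the genes that fell in absorptive-like cells were Slc40a1, Muc3 and Cldn2, while the lists of iron handling (8 of 18 lower, adjusted p = 0.461) and junctions (16 of 26 lower, adjusted p = 0.0523) did not pass. Slc40a1 fell from 37.2 ± 1.92 to 12.5 ± 1.01 CPM (-1.54 ± 0.16, adjusted p = 3.12e-04). The membrane mucin gene Muc3 fell from 94.5 ± 6.85 to 34.8 ± 7.65 (-1.39 ± 0.15, adjusted p = 3.61e-04). The pore-forming claudin gene Cldn2 fell from 22.6 ± 4.40 to 8.04 ± 4.56 (-1.63 ± 0.31, adjusted p = 0.0461). Gstp1, a glutathione transferase gene, fell from 208 ± 12.9 to 95.5 ± 32.5 (-1.12 ± 0.18, adjusted p = 0.0160). Also lower were ccdc198 (-2.47 ± 0.35, adjusted p = 0.00392), Gsdmc2 (-2.05 ± 0.34, adjusted p = 0.0161) and Gsdmc4 (-1.47 ± 0.25, adjusted p = 0.0161). A small absorptive-like cluster led by Reg1, S100g, Alpi and Slc40a1 gave 19.9% ± 5.98 of the class in young and 8.29% ± 3.08 in aged mice. Slc40a1, Muc3 and ccdc198 passed with each library left out. Gsdmc4 was lost without aged replicates 1 (adjusted p = 0.165) and 2 (0.108), and Gstp1 without young replicates 1 (0.140) and 3 (0.0819) and aged replicate 1 (0.130). Gsdmc2 was lost without any young replicate (0.0637 to 0.0676) and without aged replicate 1 (0.184). Cldn2 was lost without young replicates 1 and 3 and aged replicates 1 and 2 (0.162 to 0.256).

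Scd2, a fatty acid desaturase gene, rose from 23.1 ± 1.01 to 65.3 ± 37.5 CPM in absorptive-like cells (1.46 ± 0.28, adjusted p = 0.0461). Espn, whose product bundles actin in microvilli, rose from 15.7 ± 2.28 to 36.1 ± 6.03 (1.21 ± 0.17, adjusted p = 0.00392). Parp3 (1.06 ± 0.17, adjusted p = 0.00940) and mt-Nd6 (0.90 ± 0.15, adjusted p = 0.0161), which overlaps mt-Nd5, rose too. The fatty acid carrier gene Fabp1 stood at 3407 and 4108 CPM (0.28 ± 0.23, adjusted p = 0.740) and the apolipoprotein gene Apoa4 at 75.2 and 135.5 (0.84 ± 0.45, adjusted p = 0.576). The antibacterial lectin genes Reg3b and Reg3g were at 0.58 ± 0.45 and 0.55 ± 0.32 (adjusted p = 0.718 and 0.621). In all, edgeR called 25 of 8913 genes, 17 higher and 8 lower. Of all genes 833 had an unadjusted p under 0.05, and 14.4% showed no overlap (10% by chance). The count was 14 without young replicate 1, 14 without young replicate 3 and 65 without aged replicate 3. Espn was lost without aged replicate 1 (0.0640), and Scd2 without young replicates 1 (0.209), 2 (0.114) and 3 (0.189). Parp3 was lost without young replicates 1 (0.0572) and 3 (0.0676) and aged replicate 1 (0.114). The call of mt-Nd6 was lost without young replicates 1 and 2 and aged replicates 1 and 2 (0.0750 to 0.127). The count was 203 without a low-count filter, 75 with the replicate number as a block and 16 under each of 3 further clustering seeds.

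Camera called 7 lists in absorptive-like cells, all higher in aged mice. MHC class II rose (8 of 9 higher, median 1.53, 6 called, 7 adjusted over the list alone, adjusted p = 2.90e-17), with adjusted p = 0.212 with an estimated correlation. MHC class I rose (17 of 24 higher, 2 called, 7 adjusted over the list alone, adjusted p = 3.93e-05, and adjusted p = 0.822 with an estimated correlation). The mitochondrially encoded list rose (11 of 13 higher, 1 called, 4 adjusted over the list alone, adjusted p = 2.30e-05, and adjusted p = 0.822 with an estimated correlation). Brush border genes rose (26 of 32 higher, adjusted p = 0.00419, and adjusted p = 0.822 with an estimated correlation), with the peptidase genes Dpp4, Enpep and Mep1b and the fructose transporter gene Slc2a5 higher when adjusted over the list alone. The main cluster of the class held 73.8%, 80.7% and 85.7% of its cells in young and 89.3%, 90.6% and 95.2% in aged mice. The make-up of the class thus differed too. Its summed absorptive markers stood at 12310, 16857 and 12253 CPM in young and 18022, 20578 and 11087 in aged mice. They did not follow the share of the main cluster mouse by mouse, and aged replicate 3 lay below the young mice. Genes of lipid absorption rose (22 of 28 higher, adjusted p = 0.0115, and adjusted p = 0.822 with an estimated correlation), with Fabp2 at 0.64 ± 0.22 (adjusted p = 0.363). Cholesterol synthesis genes rose (21 of 29 higher, adjusted p = 0.00583, and adjusted p = 0.822 with an estimated correlation), with 1 called, Scd2. Wnt pathway genes rose (12 of 18 higher, adjusted p = 0.0294), with the cyclin gene Ccnd2 higher when adjusted over the list alone. It was at adjusted p = 0.822 with an estimated correlation. No list passed by that test or by fry (0 of 31, with 1 and 3 lists at an unadjusted p under 0.05). Both MHC lists and the mitochondrial list passed with each library left out (highest adjusted p 0.0135). Lipid absorption was lost without young replicates 1 (0.216) and 3 (0.110) and aged replicates 1 (0.212) and 2 (0.439). Brush border was lost without young replicate 1 (0.193) and aged replicates 1 (0.17) and 2 (0.0903), and cholesterol synthesis without young replicate 3 (0.184) and aged replicate 3 (0.307). The Wnt list was lost without young replicate 2 (0.0791) and aged replicate 3 (0.0683). The count of lists was 11 without aged replicate 1.

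In goblet-like cells, the mucus producers, single genes rose. H2-Q7, of uncertain reads beside H2-Q6, rose from 5.00 ± 1.64 to 31.9 ± 16.1 CPM (2.63 ± 0.39, adjusted p = 0.00460). Ceacam10 rose from 42.5 ± 26.3 to 171 ± 28 (1.99 ± 0.29, adjusted p = 0.00460). Cd74 rose from 69.8 ± 25 to 187 ± 80.4 (1.39 ± 0.26, adjusted p = 0.0230), and H2-Aa from 8.04 ± 4.54 to 35.7 ± 24.6 (2.14 ± 0.45, 0.0433). H2-Ab1 did not pass (104 to 126, 0.22 ± 0.17, 0.741). Esco2, needed for cohesion of sister chromatids, rose from 6.75 ± 3.23 to 23.6 ± 6.96 (1.73 ± 0.35, adjusted p = 0.0328). The linker histone gene Hist1h1b, of a near-identical family, rose from 20.9 ± 9.83 to 98.3 ± 68.7 (2.15 ± 0.43, adjusted p = 0.0285). The summed cycling markers of the class stood at 597 ± 164 CPM in young and 971 ± 506 in aged mice, and the groups overlapped. A goblet-like cluster led by Atoh1 gave 8.96% ± 3.31 of the class in young and 17.7% ± 11.8 in aged mice. H2-Q7 and Ceacam10 passed with each library left out. Cd74 was lost without young replicates 2 (0.190) and 3 (0.163) and aged replicate 1 (0.0651), and H2-Aa without any library but aged replicate 2 (0.0552 to 0.244). Hist1h1b (0.102 to 0.193) and Esco2 (0.0944 to 0.214) were lost without any library but aged replicate 3.

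AI467606 stood at 13.2 ± 4.18 CPM in young goblet-like cells and had 0 UMIs in those of all 3 aged mice (adjusted p = 0.00335). Ang4, an antimicrobial ribonuclease gene, fell from 373 ± 468 to 28.9 ± 6.05 (-3.76 ± 0.67, adjusted p = 0.0228). The claudin gene Cldn4 fell from 19.1 ± 6.63 to 2.87 ± 3.15 (-2.80 ± 0.52, adjusted p = 0.0230). Armcx3 (-1.79 ± 0.35, adjusted p = 0.0285) and Serpina1b, of a near-identical family (-1.55 ± 0.29, adjusted p = 0.0230), fell. A goblet-like cluster led by Ido1, S100a6 and Cldn4 gave 11% ± 9.63 of the class in young (7.41%, 21.9% and 3.64%) and 5.17% ± 2.94 in aged mice. The mucin gene Muc2 was at -0.49 ± 0.17 (adjusted p = 0.310). Summed goblet markers stood at 194600 ± 20445 CPM in young and 152800 ± 6226 in aged mice, without overlap. Cdkn1a stood at 84.1 ± 15.6 and 49.7 ± 8.65 (-0.82 ± 0.18, adjusted p = 0.0539). In all, edgeR called 34 of 8047 genes, 14 higher and 20 lower, and 117 (66 higher, 51 lower) with the replicate number as a block. Of all genes 803 had an unadjusted p under 0.05, and 15% showed no overlap (10% by chance). The count was 11 and 12 without young replicates 2 and 3, and 17, 13 and 146 without aged replicates 1, 2 and 3. It was 204 without a low-count filter. Ang4 was lost without aged replicate 1 (0.0943), and Cldn4 without young replicates 2 (0.190) and 3 (0.0851) and aged replicate 2 (0.0557). Armcx3 was lost without young replicates 1 and 3 and aged replicates 1 and 2 (0.10 to 0.163), and Serpina1b without any young replicate and aged replicate 2 (0.0674 to 0.104).

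In tuft-like cells, the chemosensory cells marked by Dclk1, single genes such as B2m and Ly6e rose. B2m, the class I light chain gene, rose from 191 ± 51.9 to 436 ± 114 CPM (1.17 ± 0.21, adjusted p = 0.00230). Ly6e rose from 32.8 ± 29.4 to 103 ± 20 (1.57 ± 0.33, adjusted p = 0.0288). The Schlafen gene Slfn5 rose from 10.8 ± 4.2 to 44.1 ± 8.77 (1.89 ± 0.42, adjusted p = 0.0412). The protease inhibitor gene A2ml1 (1.51 ± 0.35, adjusted p = 0.0458) and Hap1 (1.19 ± 0.27, adjusted p = 0.0458) rose too. Arhgap4 fell from 46.2 ± 10.6 to 4.31 ± 0.678 (-3.37 ± 0.50, adjusted p = 2.52e-04). Dclk1 stood at 2147 ± 389 and 2012 ± 247 (adjusted p = 0.996), and Cd74 at 39 ± 8.94 and 63.7 ± 34.6 (0.46 ± 0.34, adjusted p = 0.979). In all, edgeR called 10 of 4618 genes, 8 higher and 2 lower. Of all genes 244 had an unadjusted p under 0.05, and 10.4% showed no overlap (10% by chance). DESeq2 called 4, the test without a low-count filter 24 and the fit with the replicate number as a block 5. The count was 1 without young replicate 1, where B2m (0.143) and Arhgap4 (0.106) were lost, 17 without aged replicate 1 and 6 without aged replicate 3. Ly6e was lost without young replicates 1 (0.560) and 3 (0.0511) and aged replicate 3 (0.0776), and Slfn5 without any library but aged replicate 1 (0.0754 to 0.454). A2ml1 was lost without any library but aged replicate 2 (0.0754 to 0.260), and Hap1 without young replicates 1 and 2 and aged replicates 2 and 3 (0.101 to 0.503).

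Across the 6 tests 106 genes were called, 59 higher and 47 lower in aged mice, and 0 genes called more than once differed in direction between tests. Of the 5 classes, 20 genes were called in at least 2, 12 in at least 3 and 5 in at least 4, namely Ceacam10, H2-Aa, Ly6e, Cd74 and Tstd1.

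**Figure D3:**
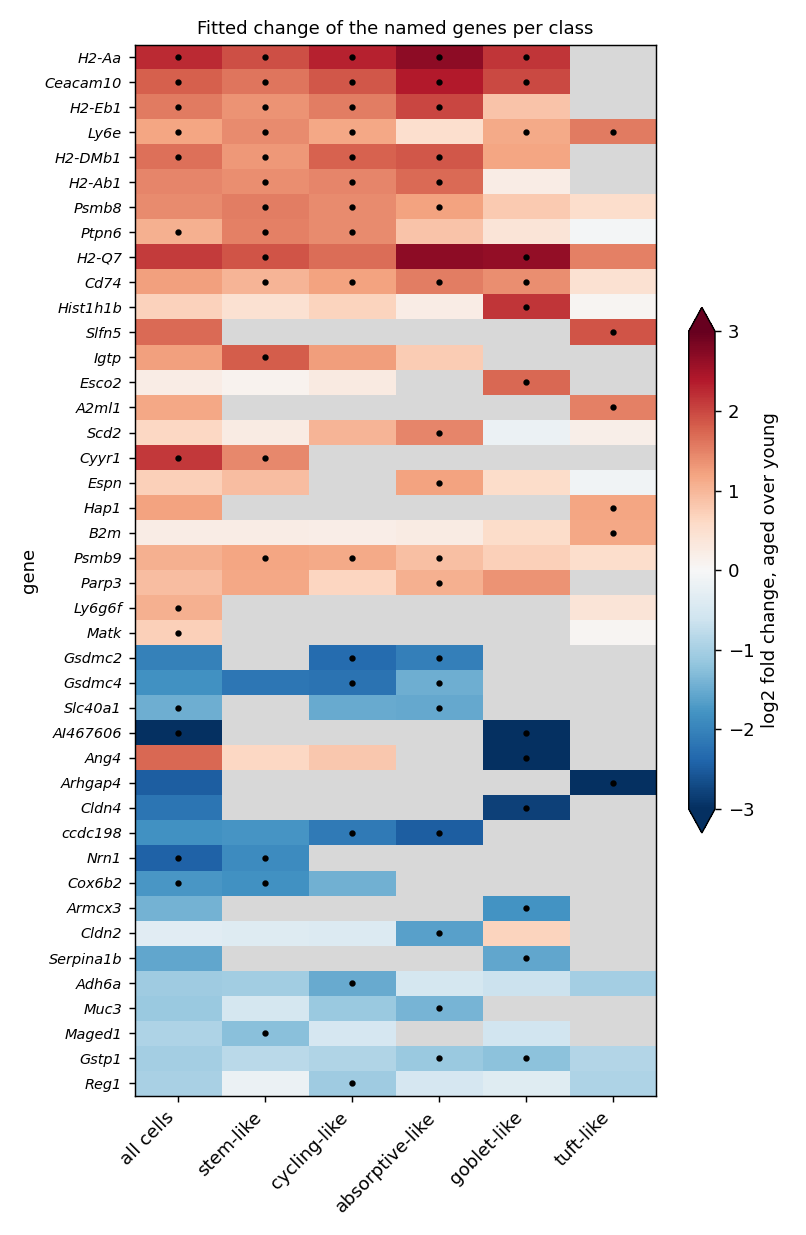
Heat map of the log2 fold change (aged over young) of the named genes over all cells and in 5 classes, with colours limited to ±3, dots for genes called by edgeR and grey for genes not tested. H2-Aa carries a dot in every column but that of tuft-like cells, with changes of 1.95 in stem-like and 2.69 in absorptive-like cells.

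Whether an age effect differed between classes was tested with the mouse as a block. Between stem-like and absorptive-like cells 5 genes differed. Ly6e was at 1.42 in stem-like and 0.51 in absorptive-like cells (difference -0.92 ± 0.11, adjusted p = 3.52e-05), and Scd2 at 0.25 and 1.46 (1.18 ± 0.17, adjusted p = 0.00101). Cldn2 was at -0.39 and -1.63 (-1.28 ± 0.24, adjusted p = 0.0300), and the secreted receptor gene Dmbt1 at -0.02 and -0.49 (-0.45 ± 0.09, adjusted p = 0.0300). Ccnd2 was at -0.21 and 0.39 (0.57 ± 0.11, adjusted p = 0.0457). Ly6e and Scd2 passed with each library left out, and Ccnd2 was lost without any young replicate and without aged replicate 2 (0.0629 to 0.270). Cldn2 was lost without young replicates 1 and 3 and aged replicates 1 and 2 (0.0587 to 0.503), and Dmbt1 without young replicates 1 (0.218) and 2 (0.166). The count was 3 without young replicate 2, 49 without aged replicate 3, 37 without a low-count filter, and 10 and 1 under the second and the third further clustering seed. Of the 5 calls, 2, 2, 1, 2 and 2 were kept under the 5 further seeds. Ly6e passed under all 5, Scd2 under the first and the fourth, Dmbt1 under the second and the fifth, and Cldn2 and Ccnd2 under none. Between cycling-like and absorptive-like cells 12 genes differed, the largest differences being those of Mgat4c (1.87 ± 0.33, adjusted p = 0.0113), Reg3b (1.32 ± 0.24, adjusted p = 0.0117), Cldn2 (-1.27 ± 0.26, adjusted p = 0.0421) and the apolipoprotein gene Apoa1 (1.23 ± 0.17, adjusted p = 5.89e-04). The count was 4 without young replicate 1, 6 without aged replicate 1, 6 without aged replicate 2, 135 without aged replicate 3 and 62 without a low-count filter. Mgat4c was lost without young replicate 1 (0.183) and aged replicate 1 (0.171), Reg3b without young replicates 1 and 3 and aged replicate 1 (0.0932 to 0.323), and Cldn2 without young replicates 1 and 3 and aged replicates 1 and 2 (0.136 to 0.505). Under each of the 5 further clustering seeds edgeR called 0 genes in that comparison (474 to 628 at an unadjusted p under 0.05). Between stem-like and cycling-like cells Reg3b (-0.84 ± 0.07, adjusted p = 6.24e-12) and the junctional adhesion gene Jaml (0.59 ± 0.11, adjusted p = 0.00496) differed. Reg3b had the opposite sign under all 5 further seeds (0.23 to 0.61), and Jaml was lost under all 5 and without aged replicates 1 (0.132) and 2 (0.171). That count was 5, 11 and 4 without young replicates 1, 2 and 3, 1 without aged replicate 2 and 21 without aged replicate 3. It was 12 without a low-count filter, and 0, 4 and 0 under the first, the third and the fifth further seed.

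The named genes lie as follows in mm10, each as start to end. On chromosome 17 lie H2-DMb1 (34153072 to 34160230), Psmb9 (34181987 to 34187764), Tap1 (34187553 to 34197225) and Psmb8 (34197721 to 34201454). The same chromosome holds H2-Ab1 (34257689 to 34269419), H2-Aa (34282744 to 34287823), H2-Eb1 (34305867 to 34316674), Ly6g6f (35080480 to 35085610), H2-Q7 (35439155 to 35443773) and Cdkn1a (29090976 to 29100727). On chromosome 7 lie Cox6b2 (4751792 to 4753094), Ceacam10 (24777206 to 24784657), AI467606 (127091359 to 127093986), Mki67 (135689784 to 135716361), Muc2 (141690340 to 141754693) and Ascl2 (142966829 to 142969264). On chromosome 6 lie Fabp1 (71199827 to 71205023), Reg3b (78370657 to 78373466), Reg1 (78422711 to 78428667), Reg3g (78466269 to 78468872), Ptpn6 (124720707 to 124738714) and A2ml1 (128539821 to 128581608). On chromosome 15 lie Gsdmc2 (63824346 to 63845177), Gsdmc4 (63891264 to 63912297) and Ly6e (74955051 to 74959905). On chromosome 10 lie Matk (81252935 to 81263365), Lgr5 (115450311 to 115587780) and Lyz1 (117287797 to 117292868). On chromosome 14 lie ccdc198 (49219588 to 49245474), Ang4 (51763878 to 51773590), Esco2 (65819038 to 65833994) and Olfm4 (79984081 to 80023139). On chromosome 1 lies Slc40a1 (45908068 to 45926523), and on chromosome 2 B2m (122147686 to 122153083). On chromosome 3 lie Dclk1 (55242364 to 55539068), Fabp2 (122895072 to 122899506) and Adh6a (138313286 to 138331134). On chromosome 4 lies Espn (152120331 to 152152371), and on chromosome 5 lie Cldn4 (134945119 to 134946934) and Muc3 (137134922 to 137149322). On chromosome 9 lie Apoa4 (46240696 to 46243459) and Parp3 (106470322 to 106476949), and on chromosome 8 Defa24 (21734494 to 21735471). On chromosome 11 lie Igtp (58199556 to 58207591), Slfn5 (82951349 to 82964840) and Hap1 (100347327 to 100356128). On chromosome 12 lie Chga (102554969 to 102565028) and Serpina1b (103728156 to 103830373), and on chromosome 13 Hist1h1b (21779883 to 21780625) and Nrn1 (36725361 to 36735131). On chromosome 16 lies Cyyr1 (85421533 to 85553397), on chromosome 18 Cd74 (60803848 to 60812652), and on chromosome 19 Gstp1 (4035407 to 4037985) and Scd2 (44293674 to 44306864). On chromosome X lie Arhgap4 (73891442 to 73921870), Maged1 (94535474 to 94542143), Armcx3 (134756595 to 134761455) and Cldn2 (139800828 to 139811386). On the mitochondrial genome lies mt-Nd6 (13552 to 14070).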

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

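The splits of the mice and the tests of technical explanations in this part were chosen only after the results were seen, except the direction test in left-out barcodes. The tests of differences between classes had been planned. The genes below stand out because their age effect differed between 2 classes by a test of the difference.

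In absorptive-like against stem-like cells, Ly6e differed by -0.92 ± 0.11 (adjusted p = 3.52e-05, higher in aged mice by 1.42 in stem-like and 0.51 in absorptive-like cells). Scd2 differed by 1.18 ± 0.17 (adjusted p = 0.00101), Cldn2 by -1.28 ± 0.24 (0.0300), Dmbt1 by -0.45 ± 0.09 (0.0300) and Ccnd2 by 0.57 ± 0.11 (0.0457). Ly6e passed in 13 of 13 alternatives (5.46e-11 to 0.00286). Dmbt1 was lost without young replicates 1 (0.218) and 2 (0.166), Cldn2 without young replicates 1 and 3 and aged replicates 1 and 2 (0.0587 to 0.503), and Ccnd2 without any young replicate and aged replicate 2 (0.0629 to 0.270). Under 5 further clustering seeds Scd2 and Dmbt1 passed in 2 each, and Cldn2 and Ccnd2 in 0. Of the 10 splits of the 6 mice, 2 gave as many genes (5 in the real split, 26 in the highest other). With 10 splits no share under 0.05 can be reached, here and for all counts below.

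In absorptive-like against cycling-like cells 12 genes differed, and under each of 5 further clustering seeds edgeR called 0 genes (474 to 628 at an unadjusted p under 0.05), so none of the 12 calls was kept there. Apoa1 differed by 1.23 ± 0.17 (adjusted p = 5.89e-04), the disaccharidase gene Sis by 0.75 ± 0.12 (0.00517), Rbp2 by 0.89 ± 0.16 (0.0117) and the lipid transfer gene Mttp by 0.64 ± 0.13 (0.0414). These were at -0.33, -0.40, -0.67 and -0.39 in cycling-like and at 0.76, 0.34, 0.26 and 0.25 in absorptive-like cells. Clca4b differed by 0.75 ± 0.11 (0.00252), Adh6a by 0.99 ± 0.18 (0.0117), Reg3b by 1.32 ± 0.24 (0.0117), Mgat4c by 1.87 ± 0.33 (0.0113) and Malat1 by 0.37 ± 0.07 (0.0117). Ly6e differed by -0.68 ± 0.12 (0.0113), Cenpw by -0.96 ± 0.20 (0.0421) and Cldn2 by -1.27 ± 0.26 (0.0421). In cycling-like against stem-like cells Reg3b differed by -0.84 ± 0.07 (6.24e-12) and Jaml by 0.59 ± 0.11 (0.00496). As many genes came from 2 of 10 splits in the former comparison (12 real, 33 highest other) and from 5 of 10 in the latter (2 real, 6 highest other). With 1 library left out in turn, Apoa1, Sis and Clca4b passed each time, but under no further seed. Without young replicate 1 Rbp2 (0.164), Mttp (0.323), Adh6a (0.149), Reg3b (0.323), Mgat4c (0.183), Ly6e (0.323), Cenpw (0.422) and Cldn2 (0.323) were lost, and Malat1 was lost without young replicate 2 (0.136). Without aged replicate 1 these genes other than Malat1 were lost (0.157 to 0.505). Jaml was lost without aged replicates 1 (0.132) and 2 (0.171) and under 5 further clustering seeds, and Reg3b between cycling-like and stem-like cells turned its sign under these seeds (0.23 to 0.61). Without young replicate 3 Rbp2, Mttp, Adh6a, Reg3b, Cenpw, Malat1 and Cldn2 were lost (0.0932 to 0.192), and without aged replicate 2 the same but Reg3b (0.0720 to 0.173).

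The split with 32, 26 and 33 genes set young replicates 1 and 3 with aged replicate 3 against the other mice. For the differences these counts are several times the real ones (5 and 12), which points to a structure of the samples. Summed absorptive markers in absorptive-like cells separated the mice in the same way. They stood at 12310, 12253 and 11087 CPM in young replicates 1 and 3 and aged replicate 3. In young replicate 2 and aged replicates 1 and 2 they stood at 16857, 18022 and 20578 CPM. Whether this is the source of the structure was not tested.

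As many genes as in the real split came from 1 of 10 splits, the real one, over all cells (34, highest other 0), in stem-like (34, 6), cycling-like (24, 2), goblet-like (34, 7) and tuft-like cells (10, 7). In absorptive-like cells they came from 2 (25, highest other 32). As many lists came from 9 splits over all cells (11, highest other 18), 8 in stem-like (7, 12), 1 in cycling-like (17, 13) and 10 in absorptive-like cells (7, 13).

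Signals also appeared in barcodes that the comparisons left out for their mitochondrial share. H2-Aa stood there at 48.7 CPM in young and 205 in aged mice. Barcodes rich in Paneth cell UMIs made up 0.175% of them in young and 0.516% in aged mice.

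MHC class II genes stood higher in aged mice. Free RNA in the droplets would add about as many Cd74 UMIs to every cell, but the mean rise per cell differed between classes. It was 20 in absorptive-like and 0.215 in tuft-like cells (ratio 92.6). In aged replicate 2 the tuft-like value did not rise (0.156 against a young mean of 0.22), and it entered the mean as a fall. Leukocytes would bring their own transcripts, but T, B and myeloid markers (22 of 36 seen) rose by 1.90 CPM against 585 CPM for Cd74 (0.325%), and CD45-positive cells had been sorted out. A filter that keeps other cells in aged libraries would leave no rise in the left-out barcodes, where the median of the list was 1.17 (1.2 in kept cells). Age stays open as a biological explanation that could not be tested against batch, since the labels give none.

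Outside the MHC lists, 29 genes changed at least 4-fold, 11 higher and 18 lower, 3 of them on chromosome X. Counting noise would leave their direction open in the left-out barcodes, but 28 of 29 (96.6%) kept it, the exception being Ang4 (38 and 39 CPM, in barcodes of all cell types, while Paneth-like cells held 3916 to 9120.2 CPM), and 25 of 29 showed no overlap (10% by chance). These barcodes come from the same mice, so differences between mice are not excluded. A genomic segment that differs between the cohorts may account for some of them and cannot be told apart, with 5 pairs within 5 Mb against a mean of 2.35 in 10000 random draws (permutation p = 0.0962). Age stays open and untested.

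Paneth-like cells were more frequent in aged libraries. Loss of young Paneth cells to the mitochondrial filter would remove the difference once the filter is dropped, but Paneth-rich barcodes then made up 0.151% in young and 0.673% in aged mice (difference 0.522 ± 0.128), so the filter is not the whole cause. It may account for part, since the ratio of aged to young was 9.48 in kept barcodes, 4.47 without the filter and 2.94 in left-out barcodes, where Lyz1 overlapped between the ages (181 ± 116 in young and 279 ± 57 CPM in aged mice). Chance differences between mice cannot be told apart with 3 against 3 mice (exact permutation p = 0.1, the lowest possible). Age stays open and untested.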

How the results depend on the processing

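The limit of 25% mitochondrial UMIs, the further clustering seeds and the fits on 1 cluster of a class were chosen only after the data had been seen. H2-Aa passed in all 21 alternatives in stem-like (adjusted p 2.52e-59 to 0.00795), all 20 in cycling-like (1.51e-82 to 0.00901) and all 19 in absorptive-like cells (2.80e-76 to 0.0130), and in 19 of 21 over all cells (2.64e-22 to 0.133). Ceacam10 and Ly6e passed in all 21 in stem-like and all 20 in cycling-like cells. Slc40a1, Muc3 and Cd74 passed in all 19 in absorptive-like cells. Less stable were Tap1 (7 of 21) and Igtp (9 of 17) in stem-like, Reg1 (7 of 20) in cycling-like and Scd2 (8 of 19) in absorptive-like cells. Called results numbered 96. For these, 1336 of 1756 values kept direction and call, 414 kept the direction only and 6 reversed. DESeq2 gave no adjusted p for 4 of the results. Of the 96, the 19 differences between classes gave 247 values, of which 116 kept both, 126 the direction only and 5 reversed. Where no reason is given, the cause was not tested.

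Without a low-count filter, which tests more genes, edgeR called 296 over all cells, 157 in stem-like, 196 in cycling-like, 203 in absorptive-like, 204 in goblet-like and 24 in tuft-like cells. It then called 37 differences between stem-like and absorptive-like, 62 between cycling-like and absorptive-like and 12 between stem-like and cycling-like cells. DESeq2 called 147 over all cells, 38 in cycling-like and 4 in tuft-like cells. With the replicate number as a block edgeR called 0 over all cells (893 at an unadjusted p under 0.05, DESeq2 without the block 147), 81 in stem-like, 39 in cycling-like, 75 in absorptive-like, 117 in goblet-like and 5 in tuft-like cells. With an estimated correlation camera called 0 lists over all cells and in each of the 5 classes, and fry called 0 over all cells and in stem-like, cycling-like and absorptive-like cells.

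Over all cells the stricter filter gave 25 genes, 6 of them shared with the 34. In stem-like cells the stricter filter, which left fewer cells, gave 10 genes, centring by library 19 and the 25% limit 20. Seeds 1, 2, 4 and 5 gave 18, 14, 21 and 20 there, and seed 1 gave 37 in cycling-like cells. In absorptive-like cells seeds 2, 3 and 4 gave 16, 16 and 16. The Lgr5-led cluster alone and seed 4 gave 11 lists each in stem-like cells, and seed 3 gave 10 in cycling-like cells. Differences between stem-like and absorptive-like cells were 10 and 1 under seeds 2 and 3, and between cycling-like and absorptive-like cells 0 under seeds 1 to 5 (edgeR, 474 to 628 at an unadjusted p under 0.05). Between stem-like and cycling-like cells they were 0, 4 and 0 under seeds 1, 3 and 5 (edgeR, 528 and 551 at an unadjusted p under 0.05 under seeds 1 and 5).

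The difference in share (aged minus young, in percent of cells) of stem-like cells turned to -0.0530 under seed 4. That of cycling-like cells turned to 1.98 under the stricter filter and to 1.84, 1.52 and 2.34 under seeds 2, 3 and 4. The enteroendocrine-like share had no value without doublet removal, after centring and under seed 2. Some fold changes reversed. Under the stricter filter these were Matk over all cells (-0.23), Olfm4 (0.0362) and Lgr5 (0.18) in stem-like cells, and Lgr5 turned in the largest cluster alone (0.029). Ascl2 in stem-like cells turned to -0.00389 after centring, to -0.0192 at the 25% limit and to -0.00719, -0.0529 and -0.0247 under seeds 1, 3 and 4. Mki67 in cycling-like cells turned to 0.0847 at resolution 2, 0.0924 after centring, 0.101 at the 25% limit, 0.0701 in the largest cluster alone and 0.0159, 0.0497, 0.0541, 0.0730 and 0.00906 under seeds 1 to 5. The difference of Reg3b between cycling-like and stem-like cells turned to 0.46, 0.61, 0.23, 0.39 and 0.48 under seeds 1 to 5.

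With 1 library left out in turn, and so fewer samples, edgeR called 0 to 77 genes over all cells (0 without young replicate 3, 875 at an unadjusted p under 0.05), 15 to 50 in stem-like, 8 to 50 in cycling-like, 14 to 65 in absorptive-like, 11 to 146 in goblet-like and 1 to 17 in tuft-like cells. Lists numbered 7 to 16 over all cells, 4 to 12 in stem-like, 13 to 19 in cycling-like and 6 to 11 in absorptive-like cells. Differences numbered 3 to 49 between stem-like and absorptive-like, 4 to 135 between cycling-like and absorptive-like and 1 to 21 between stem-like and cycling-like cells. Each of these upper gene counts but that of tuft-like cells came without aged replicate 3. The differences in share ran from -1.65 to 3.07 for stem-like, -2.31 to 0.687 for cycling-like, -6.36 to 0.0129 for absorptive-like and -3.25 to 0.0300 for goblet-like cells. They ran from 0.972 to 1.44 for Paneth-like, 0.410 to 3.53 for tuft-like and -0.565 to -0.266 for enteroendocrine-like cells. Fold changes that turned were Cdkn1a over all cells without young replicate 2 (-0.532 to 0.0540 over the 6 fits) and, in stem-like cells, Olfm4 without aged replicate 3 (-0.273 to 0.0123) and Ascl2 without aged replicate 1 (-0.0330 to 0.301). So did Mki67 in cycling-like cells (-0.0428 to 0.00833) and Apoa4 in absorptive-like cells (-0.109 to 1.21), both without aged replicate 2. Depth limited the number of genes that could be tested, which was 4618 in tuft-like cells, the smallest of the 6 sums, and 12843 over all cells.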

Other observations

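The list tests in goblet-like and tuft-like cells were chosen only after the data had been seen, and the CpG test was not. In goblet-like cells camera called 13 of 30 lists. Genes of DNA replication rose together (34 of 35 higher, median 0.74, adjusted p = 2.26e-16), with Pcna called and 15 members adjusted over the list alone, and adjusted p = 0.515 with an estimated correlation. The summed cycling markers overlapped, at 581, 768 and 442 CPM in young and 841, 1529 and 543 in aged mice, and these lists were not tested with a library left out. Genes of mitosis rose (39 of 40 higher, median 0.67, adjusted p = 2.85e-12, and adjusted p = 0.572 with an estimated correlation). MHC class II rose (6 of 7 higher, adjusted p = 9.71e-06), as did the mitochondrially encoded list (12 of 13 higher, adjusted p = 4.41e-06), both at adjusted p = 0.398 with an estimated correlation. Lipid absorption (20 of 22 lower, adjusted p = 7.20e-05, with Apoc2 called), cholesterol synthesis (26 of 30, 4.83e-04), dissociation genes (22 of 25, 7.20e-04) and fatty acid oxidation (27 of 32, 7.83e-04) fell. These were at adjusted p = 0.398, 0.572, 0.515 and 0.572 with an estimated correlation. The duodenal (9 of 11 lower, adjusted p = 0.00218), p53 (17 of 23, 0.00688), brush border (8 of 13, 0.00926), junction (18 of 26, 0.0102, with Cldn4 called) and unfolded protein lists (21 of 26, 0.0232) fell too, at adjusted p = 0.398 to 0.575 with an estimated correlation. No goblet-like list passed with an estimated correlation (camera, 0 of 30, 2 at an unadjusted p under 0.05).

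In tuft-like cells camera called 3 of 25 lists. MHC class I rose (8 of 15 higher, adjusted p = 0.00484), with B2m and H2-K1 called and 4 members adjusted over the list alone, and adjusted p = 0.808 with an estimated correlation. Type I interferon genes rose (10 of 15 higher, adjusted p = 8.80e-04, with Ifi27l2b called, and adjusted p = 0.726 with an estimated correlation). Ribosomal protein genes fell (57 of 77 lower, adjusted p = 9.35e-05, and adjusted p = 0.808 with an estimated correlation). With an estimated correlation camera called 0 of 25, with 1 at an unadjusted p under 0.05.

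Enteroendocrine-like cells numbered 7, 13 and 10 in the young and 3, 9 and 4 in the aged libraries, too few for a gene test. Their Cd74 stood at 120.2, 34.3 and 68.4 CPM in young and 976, 603 and 1842 CPM in aged mice (7, 4 and 4 against 19, 62 and 99 UMIs). In these cells the summed cycling markers stood at 157 CPM in young and 2174 in aged mice, stem cell markers at 229 and 1224, and enteroendocrine markers at 52296 and 20306. The class thus held cells with other markers in aged mice, and values of its genes cannot be set apart from that. Chga stood at 2027, 7892 and 11549 CPM in young and 0, 107 and 260.5 CPM in aged mice. Paneth-like cells numbered 5, 0 and 0 in the young and 14, 24 and 12 in the aged libraries. Their Cd74 stood at 44 CPM in young replicate 1 and at 68.4, 27.1 and 123 CPM in the aged mice.

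Markers of other cell types were low over all cells. T and NK lymphocyte markers summed to 1.39 CPM in young and 2.43 in aged mice, B and plasma cell markers to 2.88 and 4.08, and myeloid markers to 1.56 and 1.2. Endothelial markers summed to 6.52 and 6.57, stromal ones to 6.65 and 0.560 (young replicate 2 alone at 16), glial ones to 1.05 and 1.25, and erythroid ones to 0.152 and 0.108. M cell markers summed to 233 and 209 CPM.

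One hypothesis was that genes that fell at least 4-fold have CpG-rich starts, as silencing by DNA methylation might favour. The first 500 transcribed bases of these 18 genes had a mean CpG ratio of 0.522. Draws of matched genes gave 0.588 (permutation p = 0.871), so no excess was seen. Methylation was not tested.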
